A study of Caenorhabditis elegans with 4 samples.

How the data were processed

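JUN-1 is a basic leucine zipper transcription factor of Caenorhabditis elegans, related to the Jun subunit of AP-1. Chromatin immunoprecipitation with sequencing (ChIP-seq) was done on hermaphrodite worms of strain OP234, which carries a JUN-1::GFP transgene, at the L4 stage, the last larval stage. Per the labels, synchronized worms were grown at 20 °C, crosslinked with 2% formaldehyde and sonicated, and JUN-1::GFP was collected with affinity-purified goat antibodies against GFP. The series holds 4 libraries, 2 ChIP replicates and 2 input DNA replicates, grouped by their titles. The sample descriptions do not match the titles: the libraries titled ChIP are described as input DNA, and the antibody is described under the libraries titled input. The peak lists belong to the libraries titled ChIP, so the titles were followed, and whether the descriptions or the titles are right was not tested. The labels do not say whether the replicates came from separate cultures, so differences between them can be technical.

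The authors deposited 3 peak lists, 1 for each ChIP replicate and 1 combined list. Per the file headers, positions are in the WormBase WS180 genome build, and each row names PeakSeq, a program that calls regions enriched in a ChIP library over a control, as its source. Each deposited peak has a first base, a last base and a q-value written by the authors' peak caller, which is repeated in the last column of all 4152 combined, 1862 replicate 1 and 4143 replicate 2 rows. The aligner, the PeakSeq version, the read filters, the q-value limit, the use of the input libraries and the way in which the replicates were combined are not given in the sources used here. No read counts accompany the peaks, so the sequencing depth behind a value is unknown, and q-values can become smaller with depth at the same enrichment. For this reason the authors' q-value, as −log10 q, was used only to rank or describe peaks within a list, or to ask whether a peak had the identical q in another list. Ranks were compared between replicates over the matched peaks alone, which are equal in number in both lists. The rank given for a named region in replicate 1 is its place among all peaks of that list, and shows no change between lists of different lengths.

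Peaks of different lists were called shared when they overlapped by at least 1 bp. The overlap expected by chance was taken from 10000 rotations of one list's peaks along each chromosome, which keeps their spacing, with a one-sided permutation p. For values per peak, overlapping peaks were matched one to one by the number of shared bases. Rank agreement was given as Spearman's rho across matched peaks, and differences in median −log10 q were tested with 100000 permutations, two-sided. Peaks are not independent replicates, so these p-values describe the lists and not the variation between worm cultures. Shares of peaks carry exact (Clopper-Pearson) 95% intervals, which cover counting error only. Each chromosome's span ran from the first to the last called base over all 3 lists, since chromosome lengths of the WS180 build were not used here. Counts per chromosome were tested with 10000 rotations of the peak midpoints along the joined spans, two-sided. The central 33.3% of each span was tested with rotations within chromosomes. The smallest p that these rotations can give is 1e-04, and that of the permutations is 1e-05. Benjamini-Hochberg adjustment covered the 18 chromosome tests, the 21 tests of the central part, the 9 tests of X among top-ranked peaks and the 3 tests of X peak strength, each as a family.

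The tests were run on simulated lists first. With an overlap of 60% planted among 1862 simulated peaks, 59.6% was recovered. A 2-fold density planted on X gave a density ratio of 2.02 in the simulated counts. Of 20 unrelated simulated pairs of lists, 1 gave a p under 0.05 for overlap. Of 20 single simulated lists, 1 did so for X and 2 for the central part. These runs used fewer rotations and placed peaks uniformly, whereas the real peaks cluster. The rate of false positives for clustered peaks was therefore not checked. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.

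The peaks named in the text are the 25 with the smallest q in the combined list among those overlapping both replicate lists. This rule, the overlap, rank, score and X chromosome tests and their alternatives were fixed before the data were examined, except for the alternatives without peaks under 50 bp and with spans from base 1, which were added afterwards. The tests by rank, of X peak strength, of the other chromosomes, of the central part, of spacing and of peak width were added afterwards. Alternatives were an overlap of 50% of the shorter peak or of both peaks, the better-ranked 50% of a list, the longer list cut to the length of the shorter, peaks found in both replicates, each replicate list alone, lists without peaks under 50 bp, and other span limits. Planned tests of promoters, noncoding RNA genes, 10 sequence motifs, 31 gene lists and the jun-1 transgene region need a genome and annotation of the WS180 build and were not run. The gene table at hand is of another build (WBcel235), so no gene was assigned to a peak, and jun-1, fos-1, unc-119, plc-1, itr-1 and ipp-5 were not analysed here. Regions are therefore named by position, counted from 1.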

Results

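The series lists regions called as enriched in JUN-1::GFP ChIP of L4 worms, and whether they are sites of JUN-1 binding was not tested. The replicate 1 list held 1862 peaks covering 0.916 Mb, the replicate 2 list 4143 peaks covering 2.059 Mb and the authors' combined list 4152 peaks covering 2.059 Mb. Peaks were short, with median widths of 371 bp in replicate 1, 363 bp in replicate 2 and 362 bp in the combined list. The q-values ran from 3.71e-149 to 0.000232 in replicate 1 and from 2.27e-294 to 0.000303 in replicate 2. Peaks under 50 bp made up 1.24% of replicate 1, 5.02% of replicate 2 and 4.55% of the combined list. The sequencing depth of each library is unknown, as the lists give no read counts. The 2 input libraries were not analysed here, so no background level stands beside these values.

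The first question was whether the ChIP replicates found the same regions. Nearly every region of replicate 1 was found again in replicate 2, and replicate 2 held many more. Of the 1862 replicate 1 peaks, 1817 (97.6%, 95% interval 96.8 to 98.2) overlapped a replicate 2 peak. Rotated replicate 1 peaks overlapped replicate 2 in 4.1% of cases on average and in at most 227 peaks (permutation p = 1e-04, the smallest that 10000 rotations can give). With the replicate 2 list cut to its strongest peaks, as many as replicate 1 has, 1498 replicate 1 peaks (80.5%) overlapped it, against 2.34% on average after rotation. In the other direction, 1745 of 4143 replicate 2 peaks (42.1%, 40.6 to 43.6) had a partner in replicate 1. The shared regions were ranked alike, with a Spearman's rho of 0.807 between the −log10 q values of 1743 matched peaks (permutation p = 1e-05, across peaks). Peaks are not independent replicates, so this p describes the lists.

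**Figure D1:**
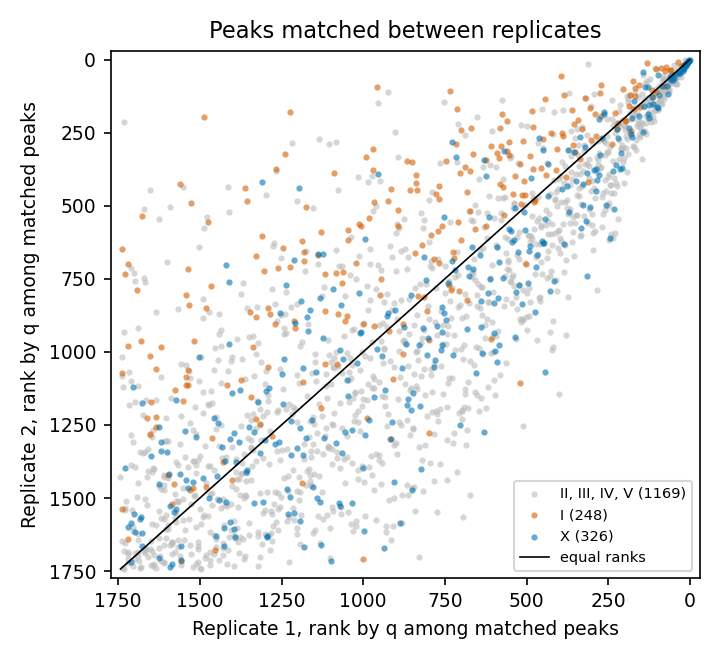
Each point is 1 of 1743 peaks matched between the replicates, placed by its rank by q among the matched peaks of replicate 1 (horizontal axis) and of replicate 2 (vertical axis), smallest q at the upper right, coloured by chromosome, with a line of equal ranks. The 248 peaks of chromosome I lie mostly above the line, at a median percentile of 52.3 in replicate 1 and 69.4 in replicate 2.

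Peaks that only 1 replicate called were mostly weak ones. In replicate 2, the 2398 unshared peaks had a median −log10 q of 4.82, against 10.8 for the shared ones, a difference of 5.95 (permutation p = 1e-05). None of the 100 strongest replicate 2 peaks and 10 of the 500 strongest were unshared. The median width of the unshared replicate 2 peaks was 290 bp, against 492 bp for the shared peaks, a difference that was not tested. In replicate 1, the 45 unshared peaks had a median −log10 q of 4.11 against 5.63, a difference of 1.51 (permutation p = 0.0132). With sharing defined as an overlap of 50% of both peaks, that difference was 0.896 (permutation p = 1e-05). Of these 45, 2 were among the 100 strongest, and the other 43 had q-values of 5.56e-06 or larger.

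The strongest regions of the combined list were a broad region on chromosome V and a series of narrower regions on X. The region with the smallest q lay at V 6220704 to 6229986, was 9283 bp wide and had a q of 2.27e-294, the same as in replicate 2. In replicate 1 it ranked at 16 and spanned 4471 bp, with a q of 1.35e-71. The next 6 regions all lay on X. The first of these, X 16929326 to 16931988 (q = 8.84e-277 combined), was the top region of replicate 1 (q = 3.71e-149), where it ran from 16929330 to 16931962. It was followed by X 8035853 to 8037002, X 4208296 to 4211470, X 12362516 to 12363716, X 14525342 to 14526648 and X 2996373 to 2997500, with combined q-values between 4.42e-193 and 1.08e-179. All 5 ranked between 2 and 7 in replicate 1. The X regions 6296058 to 6297091 and 11093668 to 11094612 ranked at 8 and 9 in replicate 1.

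Of the 25 named regions, 15 lay on X, 4 on I, 3 on II, 2 on V and 1 on III. The remaining X regions started at 16056020, 13700379, 11936980, 9465374, 5429039, 11790562 and 1626605. On the autosomes, the widest after that on V were II 10541863 to 10549619 (7757 bp), II 5335287 to 5341824 (6538 bp), I 7078584 to 7083936 (5353 bp), V 723376 to 728288 (4913 bp), III 832802 to 837244 (4443 bp) and I 9378246 to 9382170 (3925 bp). All 25 were among the top 25 of replicate 2, so their order and q-values largely repeat that list and are not pooled evidence. Of the 25, 19 were among the top 25 of replicate 1 and 23 among its top 100. The exceptions were I 9378246 to 9382170, which ranked at 139 in replicate 1 (q = 5.07e-17), and II 10541863 to 10549619, which ranked at 329 there (q = 5.8e-11).

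X held far more of the strongest regions than of the list as a whole. Over all combined peaks, 674 (16.2%, 15.1 to 17.4) lay on X, which made up 17.3% of the span (permutation p = 0.765). The X share was 18.6% in replicate 1 (permutation p = 0.587) and 16.2% in replicate 2 (permutation p = 0.771), and 18.6% among combined peaks found in both replicates (permutation p = 0.592). Among the 25 strongest peaks, however, X held 15 (60%, 38.7 to 78.9) in the combined list, 19 (76%, 54.9 to 90.6) in replicate 1 and 15 in replicate 2. Among the 100 strongest it held 37, 34 and 36, and each of these 6 counts exceeded the X share of the remaining peaks (Fisher's exact test, two-sided, largest adjusted p = 0.00026). This test treats peaks as independent, although they cluster. The combined list largely repeats replicate 2, so its counts are not separate evidence. Over the 500 strongest peaks, the X shares of 18.4% combined, 21% in replicate 1 and 18.6% in replicate 2 did not pass the test (adjusted p between 0.15 and 0.17). The median −log10 q of X peaks, 6.38, was 0.34 above that of autosomal peaks in the combined list, which did not pass the test either (permutation p = 0.0869, adjusted 0.13). The difference was 0.22 in the better-ranked 50% of that list and -0.012 among its peaks found in both replicates.

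**Figure D2:**
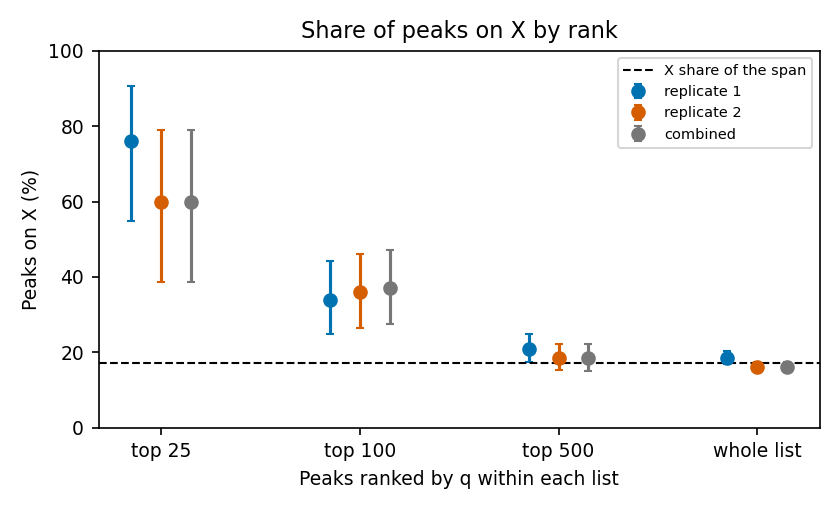
Share of peaks on X in percent (vertical axis) among the 25, 100 and 500 strongest peaks and the whole list (horizontal axis), for each list, with exact 95% intervals as bars and the X share of the span (17.3%) as a dashed line. The share is 60% or more among the 25 strongest peaks and 16.2% to 18.6% over whole lists.

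Peak numbers differed between the autosomes, and chromosome I differed between the replicates. Replicate 2 had 1036 peaks on I, or 25% of its list and 69.3 per Mb, 1.67 times the rotation mean (permutation p = 0.0002, adjusted 0.0018). Replicate 1 had 262 peaks on I, or 14.1% and 17.5 per Mb, 0.937 times the rotation mean (permutation p = 0.73). The combined list had 1034 peaks on I (24.9%, adjusted p = 0.0018 by permutation), but its peaks found in both replicates had 14.3% there. The intervals of the replicate shares, 12.5 to 15.7 in replicate 1 and 23.7 to 26.4 in replicate 2, did not overlap, and the difference between the lists was not tested otherwise. These intervals treat peaks as independent, although peaks cluster and most replicate 1 peaks were also called in replicate 2. Chromosome II held the fewest peaks in each list, 165 (8.86%) in replicate 1, 368 (8.88%) in replicate 2 and 370 (8.91%) in the combined list, on 15.3% of the span. This deficit passed the permutation test in replicate 1 (adjusted p = 0.038) and not in replicate 2 or the combined list (adjusted p = 0.27 in both). Chromosome III was above its rotation mean in replicate 1, with 376 peaks or 1.46 times that mean (permutation p = 0.0088, adjusted 0.04), and at 1.17 times in replicate 2 (adjusted 0.76). Chromosome II was at 0.576 times its rotation mean in replicate 1 and 0.58 times in replicate 2. The rotated counts on II had a standard deviation of 151 around a mean of 634.5 peaks in replicate 2, against 57.4 around 286.6 in replicate 1. The larger share of I in replicate 2 leaves less for its other chromosomes together, although the share of II was nearly the same in both replicates. Passing in 1 list alone therefore does not show a difference between the replicates on II or III. On IV and V the counts lay between 0.874 and 1.02 times the rotation mean in the 3 lists, with adjusted permutation p-values of 0.76 or more.

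**Figure D3:**
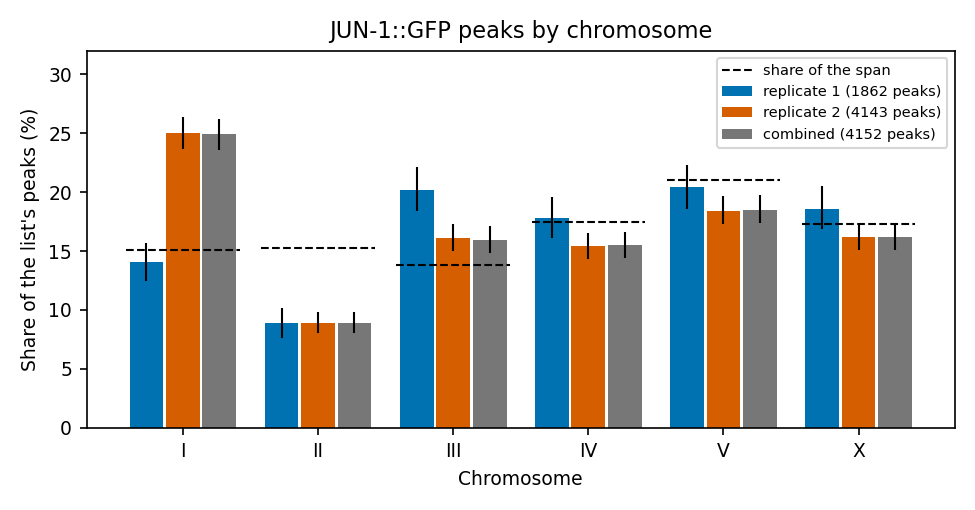
Share of each list's peaks (vertical axis, percent) on each chromosome (horizontal axis), with exact 95% intervals as bars and the chromosome's share of the span as dashed lines. Chromosome I holds 25% of replicate 2 peaks and 14.1% of replicate 1 peaks, and chromosome II holds 8.86% to 8.91% in each list.

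Peaks were more frequent in the central part of the chromosomes. The central 33.3% of the spans held 1685 of 4152 combined peaks (40.6%, 39.1 to 42.1; permutation p = 0.0007, adjusted 0.0073). The share was 40.4% in replicate 2 (adjusted 0.0073), which the combined list largely repeats, so these results are not separate. In replicate 1 it was 39.3% and did not pass after adjustment (permutation p = 0.0094, adjusted 0.066). By chromosome, the combined share was highest on V, at 47.5%, and lowest on X, at 35.2%, and no single chromosome passed the test after adjustment in any list.

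Single regions, chosen after their values were seen, also set the replicates apart. The strongest replicate 1 calls with no replicate 2 partner were a pair of neighbouring peaks on chromosome II, at 9108624 to 9123778 (15155 bp, q = 1.13e-59) and 9124038 to 9133977 (9940 bp, q = 1.13e-128). They were the widest peaks of replicate 1, where the next widest spanned 4725 bp, and ranked at 19 and 3. Together they covered 99% of a stretch of 25354 bp. Replicate 2 and the combined list had no peak in that stretch, although each had 7 peaks within 100 kb on either side, and all 4 of the other replicate 1 peaks there had a counterpart in both. The 6 strongest replicate 2 calls with no replicate 1 partner all lay on chromosome I. They included I 3246259 to 3249373 (q = 5.33e-30), I 11765672 to 11768221 (q = 1.88e-23) and I 8868413 to 8869352 (q = 2.54e-23). In all, 787 of the 1036 replicate 2 peaks on I (76%) were unshared, against 47.4% to 57.9% on the other chromosomes.

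**Figure D4:**
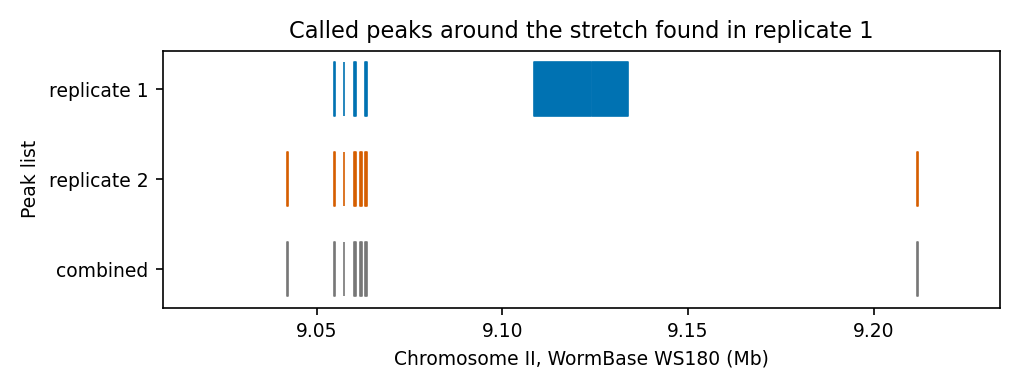
Called peaks of the 3 lists (rows) along chromosome II in WormBase WS180 coordinates (horizontal axis, Mb), drawn to scale, each bar running from the first to the last base of a peak. The 2 wide peaks at 9108624 to 9133977 appear in replicate 1 alone.

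The combined list followed replicate 2. Of its 4152 peaks, 4064 (97.9%, 97.4 to 98.3) overlapped a replicate 2 peak and 1744 (42%, 40.5 to 43.5) a replicate 1 peak. In the better-ranked 50% of the combined list, 72.5% overlapped a replicate 1 peak. With both replicate lists, 1740 peaks overlapped, 2324 overlapped replicate 2 only, 4 overlapped replicate 1 only and 84 neither. Of the combined peaks, 2688 (64.7%) had the first base, last base and q-value of a replicate 2 peak, and 0 had those of a replicate 1 peak. The q-value alone was identical in 3225 of 4051 pairs matched with replicate 2 (79.6%) and in 0 of 1742 pairs matched with replicate 1.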

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

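The alternatives for the chromosome I, central part, X strength and top-rank results, the lists without peaks under 50 bp and the span from base 1 were chosen after seeing the data. Of 42 alternatives over 11 results, 34 kept the direction and the side of the threshold by unadjusted p or, for a value with no test, stayed within its 95% interval. Some of these could hardly change. The alternatives without replicate 1 use the replicate 2 list, which the combined list largely repeats, and an overlap percentage could not change direction as counted here. The share of combined peaks on I, 24.9% on 15.1% of the span, turned to 14.3% among combined peaks in both replicate lists and ranged from 14.1% without replicate 2 to 25% without replicate 1, so the excess rests on the replicate 2 list. The share on X, which did not pass its test, turned from 16.2%, below the 17.3% of the span, to 18.6% both in peaks of both replicate lists and without replicate 2, and was 16.2% without replicate 1. The X strength difference, also not past its test, turned from 0.34 to -0.012 in peaks of both replicate lists. Shares within a list sum to a whole, so the larger share of I in the combined and replicate 2 lists lowers the share left for X there. The X share with I left out was not calculated, and the cause of the change in X strength was not tested. The share of combined peaks found in replicate 1 moved from 42% to 72.5% in the better-ranked 50% of the combined list and to 43.7% without peaks under 50 bp, and the share found in replicate 2 from 97.9% to 99.9% in the better-ranked 50%; the cause was not tested. Adjusted over the 21 tests of the central part, the share without replicate 2 (39.3%) had a permutation p of 0.066 and did not pass. The overlap of the replicates ranged from 79.2% to 99.2% over its alternatives. No paired analysis was possible because the inputs have no peak list here and the ChIP replicates form 1 group. The alternatives for the promoter, noncoding RNA, motif, gene list and jun-1 region tests were not run, as those tests need a genome of the WS180 build. Read depth is unknown for both ChIP libraries, and whether regions missing from the shorter list were unbound or undetected was not tested.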

Other observations

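All tests in this part were chosen after the results were seen. The rank measure for chromosome I replaced a ratio of −log10 q between lists, which had been seen and pointed the same way. The strongest X regions were narrower than the strongest autosomal ones, which was not so over whole lists. Among the 25 named regions, the 15 on X had a median width of 1034 bp in the combined list (790 to 3795 bp) and the 10 autosomal ones 4678 bp (1135 to 9283 bp; permutation test, two-sided, p = 0.00014). The medians were 964 bp and 2428 bp in replicate 1 (permutation p = 0.00821) and 1034 bp and 4670 bp in replicate 2 (permutation p = 0.00014). All of these width tests used the same 25 regions, chosen by the combined q, so they are not separate evidence. Over all peaks, the median width on X was larger, at 418 bp against 353 bp in the combined list and 428 bp against 361 bp in replicate 1, differences that were not tested. Sites on X that recruit the dosage compensation complex were not compared with these regions here.

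Peaks clustered along the chromosomes. In the combined list, 32.6% of peaks had another peak midpoint within 2000 bp, against 16.7% on average and at most 19.1% in 1000 uniform random placements with the same number per chromosome. In replicate 1 the share was 22.3%, against 7.61% on average and at most 10.4%.

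How the combined list came to share ends and q-values with replicate 2 was not tested, since no value here is separate from that identity. While this stays open, the combined list cannot be counted as evidence separate from replicate 2.

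The first pattern weighed is the stretch II 9108624 to 9133977, called in replicate 1 only. A replicate 2 library generally too weak to call it is argued against, since 97.7% (96.9 to 98.3) of the 1843 replicate 1 peaks with a larger q were found in replicate 2. That share nearly repeats the overlap of all replicate 1 peaks (97.6%), known before the limit was set, so it is not a separate test. It does not address a loss of signal in this stretch alone. The strain carries a jun-1 transgene, and jun-1 is a chromosome II gene, so extra copies of that gene are a candidate cause, but whether the stretch holds jun-1 was not tested on this build. Worms without the extra copies and an input that cancelled them in replicate 2 cannot be told apart, because 0 input files were used here for coverage, and neither a mislabelled library nor a biological explanation was tested.

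The second pattern weighed is the larger share of chromosome I in replicate 2. A longer list with more low-ranked peaks is argued against, as the 1862 strongest replicate 2 peaks had 24.4% (22.5 to 26.5) on I, against 14.1% (12.5 to 15.7) in replicate 1. A copy or artefact confined to part of the chromosome is argued against by 100% of its 15 bins of 1 Mb holding more unshared replicate 2 peaks (32 to 85) than the median bin of the other autosomes (17). A chromosome-wide shift of coverage or of input scaling is consistent with the matched peaks on I, whose shift in percentile by q from replicate 1 to replicate 2 had a median 14.4 percentage points above that of the other autosomes together (95% bootstrap interval 12.2 to 19), and between 11.7 (9.05 to 16.2, II) and 17.3 (15 to 22.1, III) above each of them. The bootstrap intervals rest on the peaks of 1 pair of lists, so they do not cover variation between worm cultures. The median shift was 10.9 on I, -0.803 on II, -6.4 on III, -3.5 on IV, -2.37 on V and -2.08 on X. Percentiles within 1 set of peaks must fall elsewhere when they rise on I. The source of the shift stays open, and no biological explanation was tested.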
